A study of Mus musculus with 9 samples.

How the data were processed

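Gene expression was measured on 1 array for each of 9 mouse brain samples, in 3 groups of 3: wild type with PBS, 5xFAD with PBS (vehicle) and 5xFAD with human amylin. The values analysed are the deposited log2 intensities of 35556 probe sets per array. Per the submitters' processing notes, they were made with RMA in the R package oligo; no versions are given. RMA corrects the background of each array, brings all arrays to the same quantiles and summarises the probes of a probe set. The deposited log2 values were used as they are, and the quartiles of the 9 arrays were nearly equal, with medians from 5.71 to 5.79. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

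Of the probe sets, 21789 name 1 gene symbol, 1621 name several and 12146 name none. The Entrez ID of 21698 single-symbol probe sets matched the RefSeq genes of the GRCm38.p6 assembly, which was used for names only and changed 0 symbols. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over the 9 arrays stood for it, which left 19938 genes. No gene was left out for low signal. Probe sets that name several genes or none were tested apart from the genes.

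Groups were compared with limma 3.58.1 in R 4.3.3 (with 1.17.8 of the package data.table), in 1 fit of all 9 arrays with a mean per group, 3 contrasts and an empirical Bayes prior without trend (6 residual and 3.53 prior degrees of freedom). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, without a minimum fold. Differences are given with the standard error of that fit. The 31 fixed gene lists hold 686 genes, of which 622 were measured. Of these lists, 29 were tested with camera from limma, with a preset correlation between genes of 0.01 and adjustment over the 29 lists within a comparison, and with camera with an estimated correlation and fry as alternatives. The sex-linked list served as a check of the samples, and the red blood cell list had fewer than 5 measured genes. A listed symbol was matched to its present name first and to an older name only where no gene now bears it. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined.

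The rule for named genes took, per comparison, the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, or the 5 genes with the smallest p in a direction with fewer than 5 called. To these it added the 4 members of each fixed list with the smallest p and a set of genes fixed by name, among them App, Thy1, Calcr, Ramp1, Cst7, Trem2, Cd68, Gfap and Apoe. The text names part of the genes the rule allows, picked from them after their values had been seen. Lists of olfactory bulb and hypothalamus markers were drawn up after seeing the data and were not among the 29 tested.

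The correlation of the transgene and amylin differences was set against 100 simulated sets of unchanged groups that share arrays in the same way. It, the sharing of calls and the shares of genes moved back were also set against 100 sets with the mean 5xFAD difference in both 5xFAD groups and no amylin effect, the noise being drawn for each gene apart. Simulated data tested the fit: for amylin against vehicle among 19938 genes, 18% of 50 genes changed by 0.25 log2 were recovered, 90% of 50 changed by 0.5, and 100% of 50 changed by 1 and of 50 changed by 2, with 3 false calls. There 154 changed genes were called, which loosens the adjusted p threshold, and the noise was again drawn for each gene apart. These shares are therefore not the power of the real comparison, in which 1 gene passed. With nothing changed, 0 genes were called in the comparison of vehicle with wild type, and a list shift of 0.2 was found as 0.19.

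Alternatives were quantile normalization repeated on the genes, centring each array on its median, leaving out the lowest 25% or 50% of genes by mean, a trended and robust prior, fits of only the 2 groups compared, array weights, the replicate number as a block, leaving out small and predicted genes, the mean of all probe sets of a gene, and leaving out each of the 9 arrays. Counts were also taken with a 1.5-fold minimum, at an adjusted p under 0.1, and at an unadjusted p under 0.01 with a 1.2-fold minimum. After the data were seen, the mean of the olfactory bulb list and that of the striatal list per array were each added as a term. For comparisons of single values an exact permutation test over the 10 splits of 6 arrays was used.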

Results

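Total RNA from mouse brain tissue, given as cortex in the series description, was measured on 9 Affymetrix mouse gene arrays. The samples form 3 groups of 3 biological replicates: wild-type mice that received PBS, 5xFAD mice that received PBS (the vehicle group), and 5xFAD mice that received human amylin, a peptide hormone of the pancreatic beta cell. The 5xFAD line carries human transgenes and forms amyloid plaques in the brain. The mice were about 5 months old and had been injected daily for 10 weeks. Each array gave log2 values for 35556 probe sets, and 19938 genes were tested. The median log2 value per array ranged from 5.71 to 5.79. The number of arrays limits the precision, and the median standard error (SE) of a difference between 2 groups was 0.07 on the log2 scale.

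The first comparison asks what the transgenes changed in mice on vehicle. Many genes of activated microglia, the resident macrophages of the brain, rose. Cst7, a cysteine protease inhibitor that marks microglia around plaques, averaged 9.41 ± 0.66 (SD, n = 3) in vehicle 5xFAD mice against 4.48 ± 0.20 (SD, n = 3) in wild type, a log2 difference of 4.92 ± 0.30 (SE) or 30.4-fold (limma adjusted p = 4.24e-05, probe set 10476945). Gfap, the intermediate filament of reactive astrocytes, rose by 1.63 ± 0.14 log2 (adjusted p = 0.000258). Markers of brain regions moved as well: all 13 measured striatal markers rose, while 9 of 13 hippocampal and 12 of 13 thalamic markers fell. In all, 1710 of 19938 genes changed (8.58%), 729 higher and 981 lower in vehicle 5xFAD mice, and 413 of them changed at least 1.5-fold.

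Of the 32 measured genes of disease-associated microglia, the state described around plaques, 24 rose, 0 fell and 8 did not pass, with a median log2 difference of 1.32. Adjusted over the list alone, 30 rose and 1 fell. Next to Cst7 stood the chemokine Ccl3 with 3.72 ± 0.25 log2 (SE), lysozyme 2 (Lyz2) with 2.95 ± 0.17 and Clec7a, a receptor for beta-glucans, with 2.66 ± 0.30. Tyrobp, the adaptor through which TREM2 signals, rose by 2.55 ± 0.22, and Trem2 itself by 1.62 ± 0.29 (adjusted p = 0.00871). Apoe, which carries lipids between brain cells, differed by 0.16 ± 0.05 and did not pass (adjusted p = 0.103), though it did with array weights (0.0379) and with a trended, robust prior (0.0491; 0.0379 to 0.286 over the alternatives). The shift of the list passed camera (adjusted p = 7.04e-33), but not with an estimated correlation (adjusted p = 0.0636 with an estimated correlation).

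Microglial genes of the resting state rose too. Of the 19 measured homeostatic microglia genes 15 rose, 1 fell and 3 did not pass; adjusted over the list alone 15 rose and 2 fell. Examples are Gpr34 (1.55 ± 0.16 log2), Olfml3 (1.42 ± 0.15) and the purine receptor P2ry12 (0.94 ± 0.11). The median difference was 0.89 (adjusted p = 0.123 with an estimated correlation). Of the 20 complement and Fc receptor genes 12 rose, 0 fell and 8 did not pass, and adjusted over the list alone 14 rose. C3ar1, the receptor for the complement fragment C3a, rose by 2.59 ± 0.17 log2, C1qa, a chain of the initiating C1 complex, by 1.79 ± 0.23 and C4b by 1.48 ± 0.13. The complement list also passed with an estimated correlation (adjusted p = 0.028 with an estimated correlation).

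Interferon and cytokine genes rose by smaller amounts. Of 32 interferon response genes 12 rose and 0 fell (adjusted over the list alone, 20 rose and 1 fell), among them the antiviral effectors Ifitm3 (1.05 ± 0.14 log2) and Ifit1 (0.95 ± 0.16); the list's median was 0.30 (adjusted p = 0.165 with an estimated correlation). Of 30 genes of inflammatory cytokines and NF-kB signalling 10 rose and 1 fell (adjusted over the list alone, 15 and 2), among them the lipopolysaccharide co-receptor Cd14 (1.34 ± 0.11) and the cytokine Il1a (1.36 ± 0.17). Their median was 0.22 (adjusted p = 0.17 with an estimated correlation). Of 17 antigen presentation genes 2 rose, also when adjusted over the list alone; B2m, the light chain of MHC class I, rose by 0.98 ± 0.14 (list adjusted p = 0.17 with an estimated correlation).

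Among glial lists, 9 of 24 reactive astrocyte genes rose and 1, Fkbp5, fell, with the same counts when adjusted over the list alone. The oncostatin M receptor Osmr rose by 1.60 ± 0.17 log2 and Srgn by 1.17 ± 0.09 (list median 0.20, adjusted p = 0.123 with an estimated correlation). Of 16 general astrocyte markers 0 rose and 4 fell (adjusted over the list alone, 3 rose and 7 fell). That list's shift, a median of -0.14, was lost without wild-type replicate 1 (adjusted p = 0.126) or vehicle replicate 1 (adjusted p = 0.0849), when the quantile normalization was repeated (adjusted p = 0.0997), with the lowest 25% (0.0721) or 50% (0.117) of genes left out, with array weights (0.0589), with the olfactory bulb list mean as a term (0.16), by fry (0.0518) and with an estimated correlation (adjusted p = 0.407 with an estimated correlation). Of 21 myelin and oligodendrocyte genes 5 fell and 0 rose, and 8 fell adjusted over the list alone; the receptor Gpr37 fell by 0.46 on the log2 scale (list median -0.17, adjusted p = 0.376 with an estimated correlation and 0.0568 by fry). Without wild-type replicate 1 the mean of that list went from -0.17 to -0.11. Of 20 endothelial and pericyte genes 2 rose, and 5 adjusted over the list alone; the transporter Slco1a4 rose by 0.63 ± 0.08 (list median 0.19, adjusted p = 0.179 with an estimated correlation).

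Neuronal lists moved downward except for the one of inhibitory neurons. Of 31 genes of synapses and excitatory transmission 10 fell and 0 rose, and 13 fell adjusted over the list alone. The vesicle protein Syn1 fell by 0.31 and the AMPA receptor subunit Gria1 by 0.42 on the log2 scale (list median -0.16, adjusted p = 0.219 with an estimated correlation). Of 27 activity-dependent immediate early genes 3 fell and 0 rose (7 fell adjusted over the list alone), and the transcription factors Nr4a2 and Jun fell by 1.07 and 0.85 (list median -0.26, adjusted p = 0.32 with an estimated correlation). Of 20 inhibitory neuron genes 2 rose, also adjusted over the list alone: Tac1, which is likewise abundant in striatal projection neurons, by 1.38 ± 0.15 and the homeobox gene Dlx6 by 1.00 ± 0.13 (list median 0.15, adjusted p = 0.32 with an estimated correlation and 0.0576 by fry). With the olfactory bulb list mean as a term the mean of that list fell from 0.27 to 0.07 and its shift did not pass (adjusted p = 0.251).

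Of 20 glucocorticoid-responsive genes 7 fell and 0 rose, and 11 fell adjusted over the list alone. Zbtb16, a zinc finger transcription factor induced by glucocorticoids, fell by 1.02 on the log2 scale, and Fkbp5, a co-chaperone that dampens the glucocorticoid receptor, fell by 0.57 (adjusted p = 0.000328). The list's median was -0.37 (adjusted p = 0.32 with an estimated correlation). Of 22 cholesterol biosynthesis genes 2 rose, also adjusted over the list alone, with a median of 0.07 (adjusted p = 0.518 with an estimated correlation); that shift was lost without wild-type replicate 2 (adjusted p = 0.0875) or 3 (0.0824) without vehicle replicate 2 (0.0565) or 3 (0.0649) and by fry (0.316).

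The regional markers changed on the same arrays as the microglial, synaptic and glucocorticoid-responsive lists. Of the 13 striatal genes 13 rose, also adjusted over the list alone, with a median log2 difference of 1.47 (adjusted p = 0.028 with an estimated correlation). Rgs9, a signalling regulator of striatal neurons, rose by 2.31 ± 0.09 log2 (adjusted p = 4.69e-06) and the phosphodiesterase Pde10a by 1.74 ± 0.10. Of 13 hippocampal genes 9 fell, 10 adjusted over the list alone, among them Spink8 by 1.44 and Fibcd1 by 1.08 (list median -0.81, adjusted p = 0.00981 with an estimated correlation). Of 13 thalamic genes 12 fell, also adjusted over the list alone, among them Prkcd by 1.78 and Plekhg1 by 1.27 (list median -0.83, adjusted p = 0.17 with an estimated correlation). The calcium-binding protein gene Cabp7 fell by 2.06 on the log2 scale (adjusted p = 1.12e-05), the most certain of the large decreases. Of 15 genes of infiltrating leukocytes only Cd4 rose, by 0.90 ± 0.07, also adjusted over the list alone, and the list did not shift (median 0.01, adjusted p = 0.464).

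**Figure D1:**
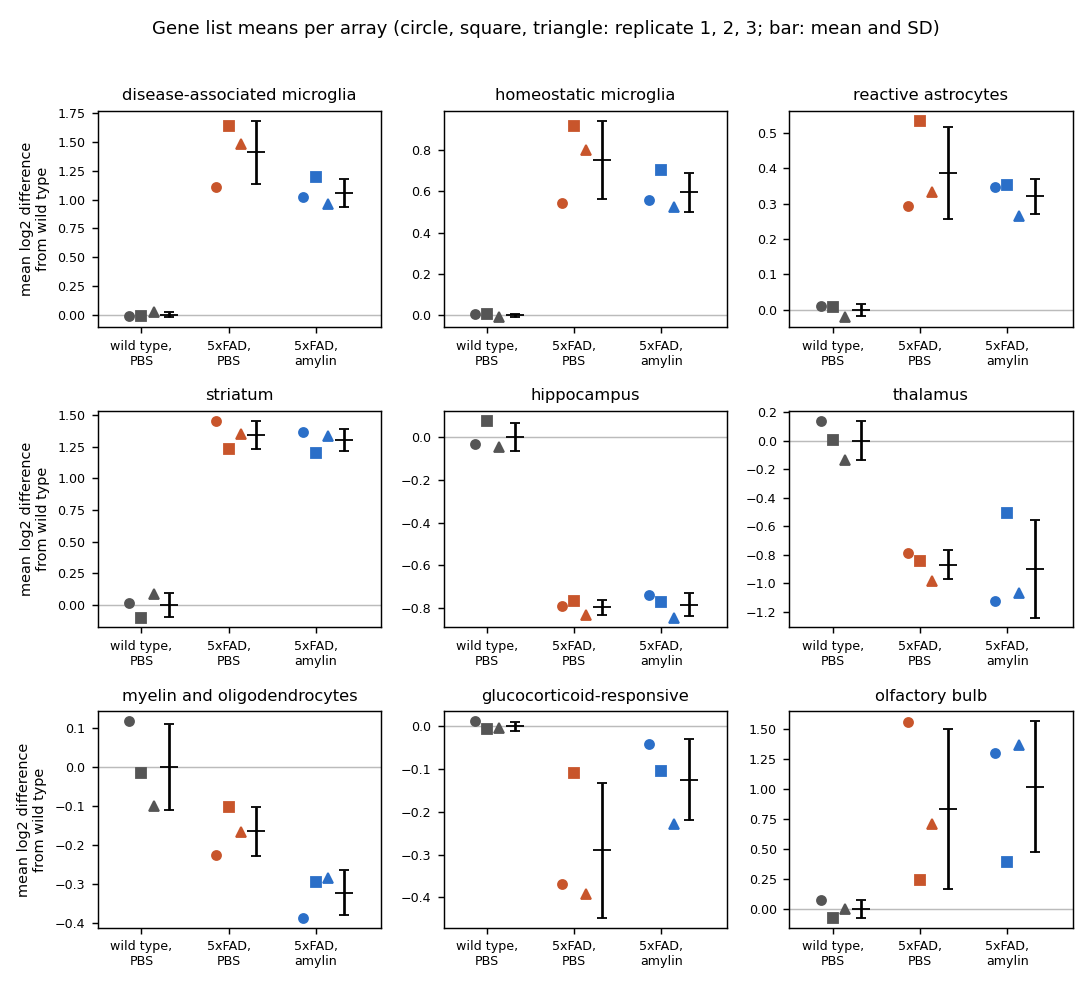
Mean log2 difference from the wild-type average for 9 gene lists, with 1 point per array, the bar giving the mean and SD of the 3 arrays of a group; the olfactory bulb list was drawn up after seeing the data. The striatal list averaged 1.34 ± 0.11 (SD, n = 3) in vehicle and 1.30 ± 0.09 (SD, n = 3) in amylin 5xFAD mice, and the hippocampal list -0.80 ± 0.03 and -0.78 ± 0.05 (SD, n = 3), apart from the wild-type arrays, and vehicle and amylin arrays overlapped in both.

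For the genes the design turns on, mouse App differed by -0.14 ± 0.05 log2 and did not pass (adjusted p = 0.139), nor did Thy1, whose promoter drives the transgenes (0.02 ± 0.07, adjusted p = 0.926). The probes were designed to mouse sequence, and the human transgenes were not measured by a probe set of their own. The calcitonin receptor gene Calcr, the core of the amylin receptor, differed by 0.44 ± 0.37 (adjusted p = 0.593), with 0.01 without vehicle replicate 1 and 0.84 without vehicle replicate 2, and its partner Ramp1 by -0.02 ± 0.04 (adjusted p = 0.883). Of 9 measured genes of the amylin receptor and peptide family 1 fell, the receptor partner Ramp3, by 0.96 on the log2 scale (adjusted p = 0.00893). Ramp3 is also on the thalamic list, and it did not pass with the olfactory bulb list mean as a term (adjusted p = 0.0656; 0.00192 to 0.0656 over the alternatives). The family's list did not shift (median -0.06, adjusted p = 0.244).

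With limma, 18 of 29 lists shifted in this comparison by camera with a preset correlation, 11 upward and 7 downward. With an estimated correlation 3 shifted, the striatal, complement and hippocampal lists, and with fry 15 did. The count of 1710 genes fell to 863, 1126 and 996 without wild-type replicate 1, 2 and 3, to 969 without vehicle replicate 3, and to 983 with the olfactory bulb list mean as a term. With the striatal list mean as a term it was 0 (1553 genes at unadjusted p under 0.05, 996.9 expected by chance), and the median SE grew from 0.07 to 0.48. That term correlated with genotype at 0.992, so its count of 0 does not show that the changes come from striatal tissue. Both terms were chosen after seeing the data.

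The second comparison asks what amylin changed within 5xFAD mice. A single gene passed: Fkbp5 was higher under amylin, with 8.31 ± 0.03 (SD, n = 3) against 7.75 ± 0.05 (SD, n = 3), a log2 difference of 0.56 ± 0.05 (SE) or 1.47-fold (limma adjusted p = 0.0233), and it averaged 8.32 ± 0.06 (SD, n = 3) in wild type. Microglial and myelin lists shifted downward under amylin by less than a log2 difference of 0.4, and the glucocorticoid-responsive list shifted upward, with no member past the threshold apart from Fkbp5. None of these shifts passed with an estimated correlation (adjusted p = 0.519 for disease-associated microglia, 0.629 for myelin and 0.631 for glucocorticoid-responsive genes with an estimated correlation), nor did any list by fry. The striatal, hippocampal and thalamic lists did not shift (adjusted p = 0.114, 0.733 and 0.681), except that the striatal list shifted downward without vehicle replicate 2 (adjusted p = 0.00169) with the quantile normalization repeated (0.0439), with the lowest 50% of genes left out (0.0398), with array weights (0.0111) and with the olfactory bulb list mean as a term (0.0167), and the thalamic list downward without amylin replicate 2 (1.46e-05) and upward with array weights (0.0347). Among 19938 genes 1375 had an unadjusted p under 0.05, with 996.9 expected by chance, and in 9.30% the groups did not overlap, with 10% expected by chance for 3 arrays against 3. The next smallest p belonged, among higher genes, to Htra1 (0.29 ± 0.05 log2), Rp9 (0.39 ± 0.06), Rhpn2 (0.31 ± 0.05) and the serotonin receptor gene Htr1a (0.43 ± 0.07), and among lower genes to Igf1, the integrin gene Itga1 (-0.41 ± 0.06), Opalin, Atp13a5 (-0.37 ± 0.06) and Fxyd1 (-0.41 ± 0.07); their adjusted p of 0.18 to 0.269 did not pass.

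Of 20 glucocorticoid-responsive genes 1 rose, Fkbp5, and 5 rose adjusted over the list alone. Zbtb16 differed by 0.59 ± 0.10 log2 (adjusted p = 0.306), the lipid droplet gene Plin4 by 0.71 ± 0.18 (adjusted p = 0.574) and Hif3a by 0.26 ± 0.07 (adjusted p = 0.66). The median difference of the list was 0.10 (camera adjusted p = 0.000208), but the adjusted p = 0.631 with an estimated correlation and its mean went from 0.17 to 0.26 without vehicle replicate 2. Zbtb16 passed with the olfactory bulb list mean as a term (adjusted p = 0.0306; 0.0306 to 0.924 over the alternatives). On the list of reactive astrocytes Fkbp5 was likewise the only gene past the threshold, also adjusted over the list alone, and that list did not shift (median -0.08, adjusted p = 0.0576), though it did when each array was centred on its median (0.045), with the replicate block (0.0194), with small and predicted genes left out (0.0461), with the striatal list mean as a term (0.00596) and without vehicle replicate 1 (0.00545) or 3 (0.0272). Without vehicle replicate 2 the mean of that list turned from -0.07 to 0.0085.

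Of 32 disease-associated microglia genes 30 had lower means under amylin and 2 had higher ones; 0 passed, and 5 fell adjusted over the list alone. The median difference was -0.33 and the list shifted downward by camera (adjusted p = 6.97e-15), but the adjusted p = 0.519 with an estimated correlation and 0.442 by fry. Igf1, a growth factor of activated microglia, came nearest with -0.49 ± 0.06 log2 (adjusted p = 0.18). The lysosomal protein gene Cd68 differed by -0.69 ± 0.15 (adjusted p = 0.495) and Cst7 by -0.72 ± 0.30 (adjusted p = 0.714, with -0.41 without vehicle replicate 2). Trem2 differed by -0.22 ± 0.29 (adjusted p = 0.893), with 0.08 without vehicle replicate 2 and 0.09 with array weights. Over the alternatives the Trem2 difference ran from -0.51 to 0.09. Without vehicle replicate 1, Cd68 passed (adjusted p = 0.0247; 0.0247 to 0.924 over the alternatives). Per array, the list averaged 1.06 ± 0.12 (SD, n = 3) above wild type under amylin and 1.41 ± 0.28 (SD, n = 3) under vehicle (exact permutation test, two-sided p = 0.2, the smallest possible being 0.1). That difference of -0.35 became -0.24 without vehicle replicate 2 and -0.50 without vehicle replicate 1.

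Other immune lists shifted downward with 0 genes past the threshold, also adjusted over the list alone. The medians were -0.24 for 19 homeostatic microglia genes, -0.20 for 20 complement and Fc receptor genes, -0.06 for 32 interferon response genes, -0.07 for 17 antigen presentation genes and -0.06 for 30 cytokine and NF-kB genes. With an estimated correlation their adjusted p were 0.631, 0.519, 0.701, 0.519 and 0.631. Examples are the Fc receptor chain Fcer1g (-0.47 ± 0.17 log2, adjusted p = 0.687; -0.25 without vehicle replicate 2) and C4b (-0.38 ± 0.13, adjusted p = 0.675). The means of the homeostatic and complement lists, -0.16 and -0.18, became -0.08 and -0.11 without vehicle replicate 2 and -0.26 and -0.28 without vehicle replicate 1. Over the alternatives the mean of the antigen presentation list, -0.067, ran from -0.097 to -0.034. That of the cytokine list, -0.089, ran from -0.146 to -0.046. The interferon list was lost with the lowest 50% of genes left out (adjusted p = 0.0866), with array weights (0.883) and with the olfactory bulb list mean as a term (0.153), the cytokine list with the lowest 50% left out (0.0819) and the antigen presentation list with array weights (0.0791).

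Of 21 myelin and oligodendrocyte genes 0 passed and 2 fell adjusted over the list alone. Opalin, a membrane protein of mature oligodendrocytes, differed by -0.77 ± 0.12 log2 (adjusted p = 0.269) and the myelin glycoprotein gene Mog by -0.38 ± 0.10 (adjusted p = 0.582). The list's median was -0.16 (adjusted p = 0.629 with an estimated correlation). Smaller downward shifts with 0 genes past the threshold, also adjusted over the list alone, were a median of -0.05 for 71 oxidative phosphorylation genes, -0.08 for 27 immediate early genes, -0.09 for 22 cholesterol biosynthesis genes and -0.05 for 20 endothelial and pericyte genes. The adjusted p were 0.701, 0.701, 0.631 and 0.629 with an estimated correlation. The synaptic list (31 genes, median 0.05) and the insulin and leptin signalling list (18 genes, median 0.06) shifted upward, with 0 genes past the threshold over all genes or adjusted over the list alone; their adjusted p were 0.631 and 0.519 with an estimated correlation. The synaptic shift, with the interferon and cytokine shifts, was lost when the quantile normalization was repeated (adjusted p = 0.343, 0.0618 and 0.0505), and the synaptic one also with the lowest 50% of genes left out (0.15). With array weights the shifts of oxidative phosphorylation (0.0545) and cholesterol biosynthesis (0.124) were lost, and with the striatal list mean as a term that of immediate early genes (0.103).

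Among genes of the amylin receptor and peptide family 0 of 9 passed, also adjusted over the list alone. Calcr averaged 5.83 ± 0.53 (SD, n = 3) under amylin and 4.99 ± 0.82 (SD, n = 3) under vehicle, a difference of 0.84 ± 0.37 log2 (SE) that did not pass (adjusted p = 0.721) and became 1.26 without vehicle replicate 1 and 0.44 without vehicle replicate 2. The list did not shift, with a median of -0.04 and a mean of 0.07 (adjusted p = 0.876). Mouse App differed by 0.06 ± 0.05 (adjusted p = 0.848).

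**Figure D2:**
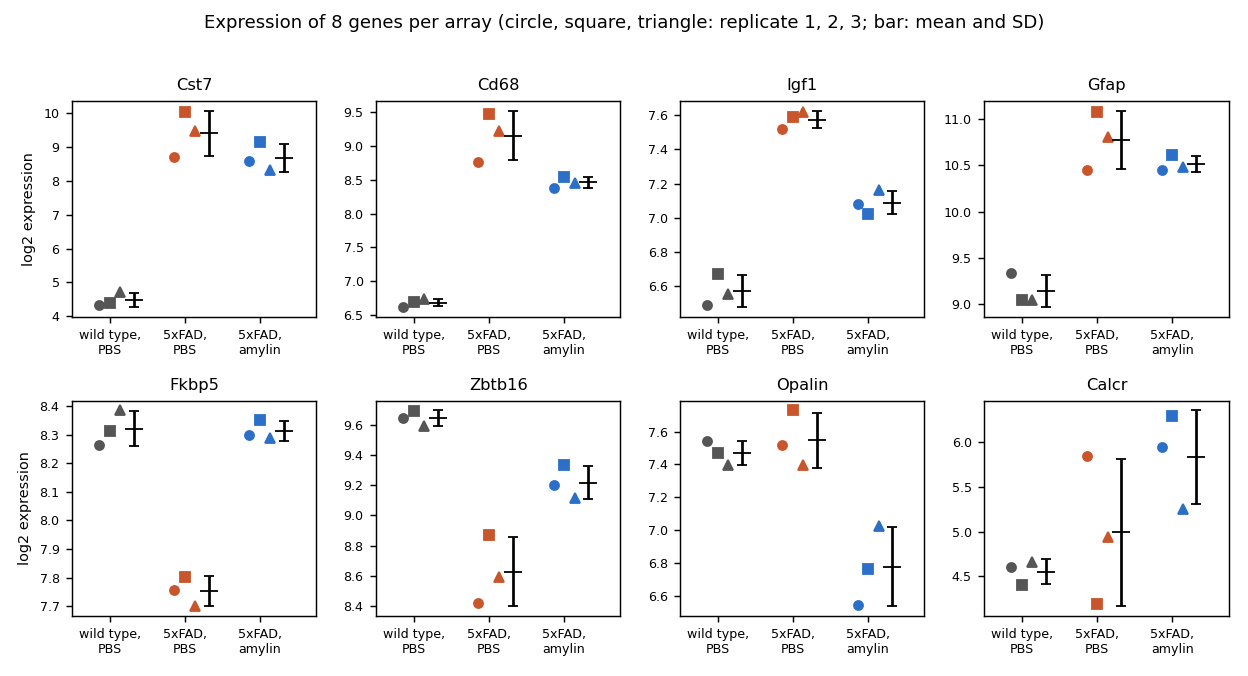
Log2 expression of 8 genes on each of the 9 arrays by group, the bar giving the mean and SD of 3 arrays. Fkbp5 averaged 8.32 in wild type, 7.75 in vehicle and 8.31 in amylin 5xFAD mice, and Calcr ranged from 4.19 to 5.84 within the vehicle group.

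With limma, 14 of 29 lists shifted between amylin and vehicle by camera with a preset correlation, 3 upward and 11 downward; with an estimated correlation 0 shifted (smallest adjusted p = 0.519), and by fry 0. Of these 14, 4 kept their call in each of the 9 fits that leave out 1 array, namely the disease-associated microglia, complement, myelin and glucocorticoid-responsive lists, and 9 lists shifted without amylin replicate 3. All these calls use the preset correlation of 0.01, while the estimated one was 0.402, 0.110, 0.355 and 0.414 for the 4 kept lists. The fits also share most of their arrays, so a kept call is no separate evidence of an amylin effect. Without vehicle replicate 1 the call was lost for oxidative phosphorylation (adjusted p = 0.0713) and synapses (0.128), and without vehicle replicate 2 for interferon (0.743, the list mean turning from -0.07 to 0.01), antigen presentation (0.0537), cytokines (0.25), synapses (0.0501) and insulin and leptin signalling (0.237). Without vehicle replicate 3 it was lost for immediate early genes (0.465, mean -0.05 after -0.11 with all arrays) and endothelium (0.232, mean -0.05 after -0.08), and without amylin replicate 1 for homeostatic microglia (0.0883), interferon (0.752), antigen presentation (0.0748), cholesterol (0.916, mean -0.01 after -0.08) and oxidative phosphorylation (0.892, mean -0.01 after -0.05, where the direction by camera, set against all other genes, turned while the mean kept its sign). Without amylin replicate 2 it was lost for synapses (0.116) and immediate early genes (0.215), and without amylin replicate 3 for these (0.2 and 0.303, the immediate early mean being -0.04, and -0.21 without amylin replicate 1), interferon (0.0842), antigen presentation (0.0615) and cytokines (0.211). The call for Fkbp5 was lost without wild-type replicate 1 (adjusted p = 0.0626), 2 (0.113) or 3 (0.0577), amylin replicate 1 (0.14), 2 (0.226) or 3 (0.116) and vehicle replicate 3 (0.224). It was also lost with the replicate number as a block (0.179), with only the 2 groups in the fit (0.288) and with the striatal list mean as a term (0.0968), while its difference stayed between 0.53 and 0.59; over the alternatives its adjusted p ran from 0.00709 to 0.288. Without vehicle replicate 1, 7 genes passed, and without vehicle replicate 2, 3 did.

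The third comparison sets amylin-treated 5xFAD mice against wild type. Cst7 had the largest rise of a called gene, averaging 8.69 ± 0.42 (SD, n = 3) against 4.48 ± 0.20 (SD, n = 3), a log2 difference of 4.21 ± 0.30 (SE) or 18.5-fold (limma adjusted p = 0.000163). Ccl3 rose by 3.20 ± 0.25 log2, the perforin-like macrophage gene Mpeg1 by 2.70 ± 0.23, Lyz2 by 2.32 ± 0.17 and Gfap by 1.37 ± 0.14. Regional markers moved as under vehicle: Rgs9 rose by 2.21 ± 0.09 (adjusted p = 7.04e-06) and all 13 striatal genes rose. In all, 1039 genes changed (5.21%), 468 higher and 571 lower under amylin, and 315 of them changed at least 1.5-fold.

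Of 32 disease-associated microglia genes 17 rose and 0 fell (23 rose adjusted over the list alone), with a median of 0.88 and an adjusted p = 0.133 with an estimated correlation. Clec7a rose by 1.98 ± 0.30 log2, Tyrobp by 1.90 ± 0.22 and Cd68 by 1.78 ± 0.15. Itgax, an integrin of activated microglia, differed by 0.72 ± 0.31 (adjusted p = 0.249), with 0.47 without amylin replicate 2, and passed only with the olfactory bulb list mean as a term (adjusted p = 0.0174; 0.0174 to 0.536 over the alternatives). Of 19 homeostatic microglia genes 15 rose and 0 fell (16 and 1 adjusted over the list alone), among them Gpr34 by 1.23 ± 0.16 and the colony-stimulating factor receptor Csf1r by 0.79 ± 0.12 (list median 0.63, adjusted p = 0.15 with an estimated correlation). Of 20 complement and Fc receptor genes 8 rose and 0 fell (12 rose adjusted over the list alone); C3ar1 rose by 2.21 ± 0.17 and C1qa by 1.40 ± 0.23 (list median 0.49, adjusted p = 0.0503 with an estimated correlation).

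Of 32 interferon response genes 7 rose (15 adjusted over the list alone; median 0.28, adjusted p = 0.183 with an estimated correlation). Of 30 cytokine and NF-kB genes 8 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.237 with an estimated correlation and 0.112 with the lowest 50% of genes left out), and Cd14 rose 2.30-fold (adjusted p = 0.00041). Of 24 reactive astrocyte genes 6 rose (7 adjusted over the list alone), among them Osmr by 1.40 ± 0.17 (list median 0.13, adjusted p = 0.165 with an estimated correlation). B2m rose by 0.94 ± 0.14, while the antigen presentation list did not shift (adjusted p = 0.204), except with the olfactory bulb list mean as a term (0.038).

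Of 27 immediate early genes 9 fell and 0 rose (17 fell adjusted over the list alone); Nr4a2 and Jun fell by 1.16 and 0.68 on the log2 scale (list median -0.34, adjusted p = 0.195 with an estimated correlation). Of 21 myelin and oligodendrocyte genes 8 fell and 0 rose (15 fell adjusted over the list alone), among them Gpr37 by 0.62 (list median -0.27, adjusted p = 0.173 with an estimated correlation). Of 20 inhibitory neuron genes 4 rose (7 rose and 2 fell adjusted over the list alone), with Tac1 by 1.57 ± 0.15 and Dlx6 by 1.13 ± 0.13 (adjusted p = 0.189 with an estimated correlation). Over the alternatives the mean of that list, 0.38, ran from 0.15 to 0.46, and the Tac1 difference from 1.13 to 1.73. Of 31 synaptic genes 2 fell (1 rose and 8 fell adjusted over the list alone); the list's median was -0.09, its adjusted p = 0.388 with an estimated correlation, and its shift was lost without wild-type replicate 3 (adjusted p = 0.0914) or amylin replicate 1 (adjusted p = 0.0993), when the quantile normalization was repeated (adjusted p = 0.0535) and with the olfactory bulb list mean as a term (adjusted p = 0.137). Of 20 endothelial and pericyte genes 1 rose, also adjusted over the list alone (list median 0.08, adjusted p = 0.425 with an estimated correlation); that shift was lost without wild-type replicate 2 (adjusted p = 0.151) or amylin replicate 1 (adjusted p = 0.0916), with the lowest 25% of genes left out (0.0572), with array weights (0.0518), with the olfactory bulb list mean as a term (0.322) and by fry (0.183).

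On the same arrays the 13 striatal genes rose with a median of 1.48, also adjusted over the list alone (adjusted p = 0.0326 with an estimated correlation). Of 13 hippocampal genes 9 fell, also adjusted over the list alone, with Prox1, a transcription factor of dentate granule cells, fallen by 1.39 and Spink8 by 1.27 on the log2 scale (list median -0.81, adjusted p = 0.00765 with an estimated correlation). Of 13 thalamic genes 12 fell, also adjusted over the list alone (list median -0.84, adjusted p = 0.173 with an estimated correlation). Cabp7 fell by 2.01 (adjusted p = 1.41e-05).

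With limma, 14 of 29 lists shifted in this comparison by camera with a preset correlation, 9 upward and 5 downward, 2 with an estimated correlation (striatal and hippocampal) and 15 by fry. The count of 1039 genes became 447, 602 and 596 without wild-type replicate 1, 2 and 3 and 548 without amylin replicate 3. It was 449 with the olfactory bulb list mean as a term, 0 with the striatal list mean as a term (1358 genes at unadjusted p under 0.05, 996.9 expected by chance) and 1723 at an adjusted p under 0.1. The striatal term correlated with genotype at 0.992 and raised the median SE from 0.07 to 0.46. Its count of 0 therefore does not show that the changes come from striatal tissue.

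The comparisons of both 5xFAD groups with wild type shared 383 higher and 475 lower genes, and 0 genes changed in opposite directions. Independent calls would share 17.1 and 28.1. As a share of the genes called under vehicle these were 52.5% and 48.4%. Simulated groups with the mean 5xFAD difference in both 5xFAD groups and no amylin effect shared 891 and 1111 genes on average, or 73.8% and 73.0% of 1208 higher and 1523 lower genes called under vehicle, against 729 and 981 such genes observed. The simulations draw the noise of each gene apart from that of the others and called more genes than observed, so they are a limited reference. Both comparisons use the same wild-type arrays, so part of the excess over independent calls may come from the shared controls. Across genes, which are not independent replicates, the differences correlated with Pearson r = 0.875, against 0.496 in simulated unchanged groups that share the wild-type arrays in the same way.

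Whether amylin moved genes back toward wild type was asked from the 2 differences that share the vehicle arrays. Across genes, r between the transgene difference and the amylin difference was -0.416, against -0.502 in simulated unchanged groups and -0.193 (range -0.234 to -0.159) in simulations with the transgene effect alone. The observed r lies between these references, the first of which has no transgene effect while the second called more genes than observed, so r does not settle the question. The covariance was -0.0101, against -0.00373 (range -0.00436 to -0.00334) and -0.00372 (range -0.00459 to -0.003). Of the genes called higher in vehicle 5xFAD mice 82.7% had lower means under amylin than under vehicle, and of those called lower 80.6% had higher means. These shares are raised by the selection of genes on the shared vehicle arrays, and the simulations without an amylin effect, with the limits given, gave 63.3% (range 60.1 to 66.9) and 63.8% (range 59.9 to 67.1). Chosen instead on the amylin arrays, a selection that works the other way, 56.8% of the genes called higher against wild type had lower means under amylin than under vehicle, and 51.0% of those called lower had higher means, against 37.0% (range 33.9 to 40.6) and 36.7% (range 33.9 to 40.4) in these simulations. The observed shares lie above the simulated ones, but variation common to many genes on 1 array, which the simulations lack, was not ruled out as the reason. The correlation across genes was -0.520 without vehicle replicate 1 and -0.320 without amylin replicate 2.

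**Figure D3:**
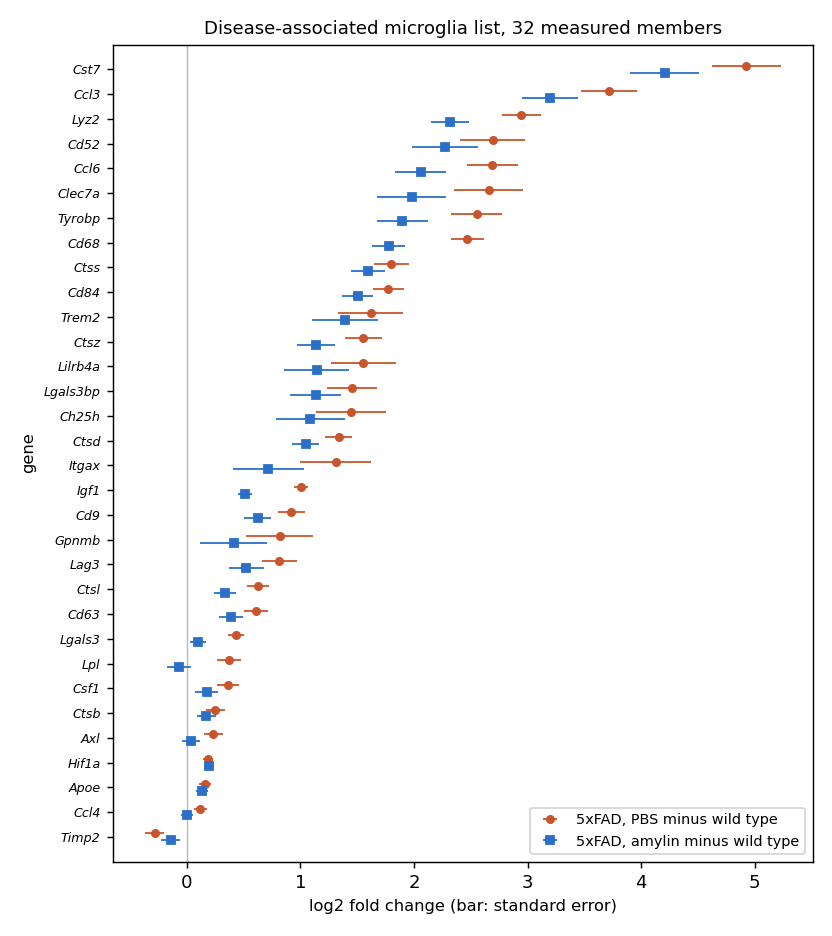
Log2 difference from wild type of the 32 measured disease-associated microglia genes in vehicle and in amylin-treated 5xFAD mice, with bars for the standard error. The vehicle difference was the higher one in 30 of the 32 genes, and 0 of them passed the test between amylin and vehicle.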

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

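The tests of the transgenes as the source of the regional shifts, of striatal tissue and of leukocytes were chosen after the result was seen, as were the olfactory bulb list and the 4 relations to it. Probe sets outside the tested genes carried signals that differ between genotypes. Of 12146 probe sets that name no gene, 12 were higher and 2 lower in vehicle 5xFAD mice than in wild type by limma (1200 at unadjusted p under 0.05, 607.3 expected by chance), and 12 were higher and 3 lower under amylin. Of 1621 probe sets that name several genes, 114 were higher and 23 lower in vehicle 5xFAD mice than in wild type, and 13 were higher and 3 lower under amylin. At unadjusted p under 0.05 by limma these comparisons gave 311 and 229, with 81.05 expected by chance, and so lay closer than the adjusted counts. Between amylin and vehicle 0 of either kind passed, with 639 and 128 at unadjusted p under 0.05 against 607.3 and 81.05 expected by chance.

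The means of the striatal list were higher, and those of the hippocampal and thalamic lists lower, on all 6 5xFAD arrays than on the wild-type arrays. If the dissected tissue differed in regional makeup from array to array, the genes of a regional list should vary together within groups. That held in 2 of the 3 lists, striatum (mean residual correlation 0.398, against 0.0938 at the 95th percentile of 1000 random lists) and thalamus (0.709 against 0.102), and not in the hippocampal list (0.0118 against 0.119). Some lists that are not regional came near the striatal value, such as homeostatic microglia (0.411) and glucocorticoid-responsive genes (0.414). Others were lower, down to -0.0106 for amyloid precursor processing. A high correlation is thus not specific to regional makeup. A low one does not exclude it, because a difference in makeup shared by all arrays of a genotype leaves no such correlation. Regional makeup and an effect of the transgenes on these genes cannot be told apart, because they go together on all 9 arrays: 0 arrays had a striatal mean inside the range of the other genotype. The olfactory bulb list, drawn up after seeing the data, also lay higher on all 6 5xFAD arrays than on the wild-type arrays. It ran from -0.07 to 0.07 in wild type, from 0.24 to 1.56 under vehicle and from 0.39 to 1.36 under amylin. Regional signal thus also varied inside a genotype. Either explanation may account for the shift of the regional lists.

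Microglial genes were higher in vehicle 5xFAD mice than in wild type. The rise of 3 members, Cst7, Ccl3 and Lyz2, exceeded the largest striatal rise, that of Rgs9 (2.31 ± 0.09 log2), by more than 2 standard errors. The 21 other called members did not exceed it by that much, though some, such as Clec7a (2.66) and Tyrobp (2.55), had a larger rise. The fold of a striatal marker gives only a lower limit of how far the striatal share rose. Signal from other tissue and background adds to it in both groups, so more striatal tissue stays open for all of these members. Within the vehicle group the striatal means (1.45, 1.23 and 1.35 on replicates 1, 2 and 3) did not rise with those of the disease-associated microglia list (1.11, 1.64 and 1.48). Under amylin, replicate 2 had the lowest striatal mean and the highest microglial mean (1.19, against 1.02 and 0.96 on replicates 1 and 3). Replicates 1 and 3 went the other way, with both means higher on replicate 1 (striatal 1.37 against 1.33). The microglial means thus did not follow the striatal ones within either 5xFAD group. With 3 arrays per group this cannot decide the question. The striatal means spread about as little there (SD 0.11 and 0.09) as in wild type (0.09). A striatal share raised on all 5xFAD arrays alike would leave no such relation. The leukocyte list averaged a change of 0.0415. Its 15 measured markers lay low in the range of the arrays (median 4.27 in wild type), where a small share of such cells can go unseen. Blood leukocytes therefore stay open as a part of the rise. The homeostatic microglia list rose as well, by a mean of 0.75, with 15 of 19 genes higher and 1 lower. That argues against blood leukocytes as the only source of the microglial signal. A response of microglia to the transgenes may likewise account for the rise, and it cannot be told apart from more striatal tissue or a part from leukocytes.

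The disease-associated microglia list was lower under amylin than under vehicle, with a mean shift of -0.35. With the olfactory bulb list mean as a term the shift was -0.29, or 82.9% of its size, which argues against different olfactory bulb content as its whole cause. Left out in turn, the 6 arrays gave shifts from -0.50 to -0.24, the weakest without vehicle replicate 2 (67.1% of its size), which argues against 1 array as its source. Over the 6 arrays from 5xFAD mice the relation to the olfactory bulb list mean passed for 0 of 4 lists after adjustment: Pearson r was -0.788 for disease-associated microglia (permutation p = 0.075, adjusted 0.15; rho = -0.771, permutation p = 0.103), -0.902 for homeostatic microglia (permutation p = 0.0347, adjusted 0.139; rho = -0.886, permutation p = 0.0333), -0.523 for myelin (permutation p = 0.282, adjusted 0.376; rho = -0.314, permutation p = 0.564) and -0.321 for glucocorticoid-responsive genes (permutation p = 0.503; rho = -0.314, permutation p = 0.564), and without vehicle and amylin replicate 2, the farthest, it was -0.864, -0.952, -0.480 and 0.303, so olfactory bulb content stays open as part of the cause. An effect of amylin on microglia may contribute; the list did not pass with an estimated correlation (adjusted p = 0.519).

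Each comparison of 6 arrays has 10 splits into 3 and 3, which cannot give a share under 0.05. For vehicle against wild type, 1 split gave as many genes (1710, the highest other 0) and 2 as many lists (18, the highest other 19). For amylin against wild type, 1 gave as many genes (1039, the highest other 0) and 2 as many lists (14, the highest other 17). For amylin against vehicle, 2 gave as many genes (1, the highest other 70) and 2 as many lists (14, the highest other 15). The split with 70 genes and 15 lists sets amylin replicates 1 and 3 and vehicle replicate 1 against the others, and it points to a structure of the samples. Those 3 arrays had olfactory bulb list means of 1.30, 1.36 and 1.56, against 0.39, 0.24 and 0.71 on the others; that list was drawn up after the data were seen, so its means describe the split and are no separate evidence for its cause.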

How the results depend on the processing

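The terms for the olfactory bulb and striatal list means were chosen after the data were seen; the cause of the changes below was not tested unless stated. Leaving out 1 array, which also lowers the number of samples, gave 863 to 1779 changed genes for vehicle against wild type (1710 with all arrays), 0 to 7 for amylin against vehicle (1) and 447 to 1086 for amylin against wild type (1039), and 17 to 18, 9 to 15 and 14 to 16 shifted lists (18, 14 and 14). The correlation of transgene and amylin differences ran from -0.520 to -0.320 (-0.416). Where a leave-out kept 2 arrays in a group, the spread was pooled over groups. For amylin against vehicle the gene count was 0 with only the 2 groups in the fit, 0 with the replicate block, 0 with a 1.5-fold minimum, 0 with the striatal term, 2 with the olfactory bulb term and 140 at an unadjusted p under 0.01 with a 1.2-fold minimum. For vehicle against wild type it was 413 with the 1.5-fold minimum, 983 with the olfactory bulb term and 0 with the striatal term; for amylin against wild type 315, 449 and 0, and 1723 at an adjusted p under 0.1. With an estimated correlation 3, 0 and 2 lists shifted, and with fry 0 for amylin against vehicle. With the striatal term 11 lists shifted for vehicle against wild type, and the correlation was -0.556. That term correlated with genotype at 0.992 and raised the median standard error from 0.07 to 0.48 and 0.46 in the comparisons with wild type, where 10 of 47 and 3 of 24 named calls and 6 of 18 and 4 of 14 list calls turned sign, 1 and 1 of the lists passing in the other direction. Between amylin and vehicle the thalamic list turned to a mean of 0.16 with array weights (adjusted p = 0.0347), and the oxidative phosphorylation list had a mean of -0.0143 without amylin replicate 1 (adjusted p = 0.892), its camera direction turned, and of -0.0767 without amylin replicate 3. The replicate block gave 1638, 0 and 1059 genes, 18, 16 and 14 lists and a correlation of -0.416. Same-numbered arrays of different groups correlated at -0.0556 to 0.183 in their deviations, above 0.1 in 4 of 9 pairs. By mean correlation with the arrays of the other groups, 7 of 9 arrays lay closest to their own number among the 3 numbers. The numbers were not taken as pairs because these correlations are weak, but a factor shared by same-numbered arrays was not excluded. Normalization, signal filters, prior, array weights and probe set choices kept the gene counts within 1.5 times. Xist lay between 9.85 and 10.4 and Eif2s3y between 2.49 and 2.61 on all 9 arrays, so the term for sex was not run. With the lowest 50% of genes left out, 1318 of the 1710 and 805 of the 1039 genes were still among those called. For the striatal term single genes and lists were tabulated only between amylin and vehicle, because that term and genotype are nearly 1 variable.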

Other observations

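The hypothalamus and olfactory bulb lists, and the term made from the latter, were chosen after the data were seen. Genes of metabolism and growth signalling moved singly. Of 19 glycolysis genes 1 rose and 4 fell in vehicle 5xFAD mice against wild type (1 and 5 adjusted over the list alone), among them the neuronal glucose transporter Slc2a3 by 0.37 on the log2 scale (limma adjusted p = 0.00415). Of 71 oxidative phosphorylation genes 3 fell and 0 rose (1 fell adjusted over the list alone); Sdha, of respiratory complex II, fell by 0.24 (adjusted p = 0.0125), though not without wild-type replicate 1 (0.0542) or with the olfactory bulb list mean as a term (0.0765; 0.00461 to 0.0765 over the alternatives). Neither list shifted (adjusted p = 0.112 and 0.75), but glycolysis did without vehicle replicate 2 (0.0488) and by fry (0.0374), and oxidative phosphorylation shifted upward when the quantile normalization was repeated (adjusted p = 0.0261). Of 18 insulin and leptin signalling genes 3 rose and 2 fell (3 and 3 adjusted over the list alone); Tsc2, a brake on mTOR, fell by 0.31 (adjusted p = 0.00493), the transcription factor Foxo1 rose by 0.39 ± 0.06 (adjusted p = 0.00617; 0.0563 with the olfactory bulb list mean as a term, in a range of 0.00155 to 0.0563), and the list did not shift (adjusted p = 0.526). Of 23 genes of amyloid precursor processing and clearance 2 rose and 1 fell, also adjusted over the list alone. Mme, the amyloid-degrading peptidase neprilysin, rose by 0.56 ± 0.09 (adjusted p = 0.00528), though not with the olfactory bulb list mean as a term (adjusted p = 0.0503; 0.00171 to 0.0503 over the alternatives). That list did not shift (median -0.06, adjusted p = 0.925). In this comparison all 13 striatal genes rose as well. Whether the changes of single genes such as Mme and Foxo1 follow regional makeup was not tested.

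Other lists held few changes between vehicle 5xFAD mice and wild type. Of 15 circadian clock genes 1 rose and 1 fell, also adjusted over the list alone; the repressor Nr1d1 fell by 0.46 on the log2 scale (adjusted p = 0.00709; list adjusted p = 0.978). Of 26 genes of unfolded protein and heat shock responses 1 rose, and 0 adjusted over the list alone (list adjusted p = 0.526; 0.0295 with the olfactory bulb list mean as a term), and of 11 oligodendrocyte precursor genes 0 passed (list adjusted p = 0.164). Of 14 meningeal fibroblast genes 1 fell, also adjusted over the list alone, the matrix proteoglycan gene Dcn by 1.03 (list adjusted p = 0.526; 0.00982 with the olfactory bulb list mean as a term). Of 14 choroid plexus genes 1 rose and 1 fell, also adjusted over the list alone, the latter being Otx2, which fell by 0.62 (adjusted p = 0.00871; 0.0781 with the olfactory bulb list mean as a term, in a range of 0.00298 to 0.0781; list adjusted p = 0.925).

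Between amylin and vehicle the lists of astrocyte markers, glycolysis, oligodendrocyte precursors, amyloid precursor processing, unfolded protein and heat shock, circadian clock, meningeal fibroblasts, choroid plexus, leukocytes and inhibitory neurons did not shift (adjusted p = 0.322, 0.899, 0.733, 0.831, 0.733, 0.719, 0.535, 0.282, 0.681 and 0.0576), with 0 genes past the threshold. The inhibitory neuron list shifted upward without vehicle replicate 1 (adjusted p = 0.00133), amylin replicate 2 (0.00265) or wild-type replicate 3 (0.0465), with the replicate block (0.0101), with the olfactory bulb list mean as a term (0.0314) and with the striatal one (0.000534), and the unfolded protein and heat shock list without amylin replicate 1 (0.000762). Between amylin-treated 5xFAD mice and wild type the lists of astrocyte markers, oxidative phosphorylation, glycolysis, oligodendrocyte precursors, amyloid precursor processing, amylin receptor family, insulin and leptin signalling, cholesterol biosynthesis, unfolded protein and heat shock, circadian clock, glucocorticoid-responsive genes, meningeal fibroblasts, choroid plexus and leukocytes did not shift either (adjusted p = 0.129, 0.0764, 0.058, 0.112, 0.819, 0.178, 0.238, 0.779, 0.389, 0.691, 0.0802, 0.246, 0.376 and 0.53). Some of these lists shifted under single alternatives. Glycolysis did so by fry (0.0457), with a trended, robust prior (0.0318), with the lowest 50% of genes left out (0.0322), with the mean of all probe sets (0.033) and without wild-type replicate 3 (0.0467) or amylin replicate 2 (0.0403) or 3 (0.0213), each time downward. Oxidative phosphorylation shifted downward without wild-type replicate 3 (0.0198) or amylin replicate 3 (3.84e-05), and unfolded protein and heat shock upward without amylin replicate 1 (0.000882), as did cholesterol biosynthesis (0.0267). Astrocyte markers (0.0444 without wild-type replicate 3), choroid plexus (0.0311 without wild-type replicate 2), meningeal fibroblasts (0.049 without amylin replicate 1) and glucocorticoid-responsive genes (0.0217 without vehicle replicate 2, 0.0318 with only the 2 groups in the fit) shifted downward, as did the amylin receptor family by fry (0.0457). With the olfactory bulb list mean as a term, oxidative phosphorylation (0.0378), the amylin receptor family (0.038), unfolded protein and heat shock (0.00506) and meningeal fibroblasts (0.000403) shifted. The added hypothalamus list stood at 0.66 above wild type on amylin replicate 2 and between -0.37 and 0.05 on the other 8 arrays.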
